A study of Homo sapiens with 24 samples.

How the data were processed

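The deposited table holds whole read counts per gene for 24 libraries of the 2 cell lines. Poly(A) RNA was made into stranded TruSeq libraries and sequenced paired-end on a HiSeq3000, per the labels' protocols. FastQC, STAR 2.5.3a, featureCounts 1.15.2 and DESeq2 1.18.1 were used with hg19, per the submitters' processing notes, which state neither the order of the steps nor whether counting used strand. Overlapping antisense genes can therefore not be told apart, and values of genes with near-identical copies (KRT6A and UPK3B among those named) are uncertain. The authors' counts were whole numbers for 39786 genes with gene length, coordinates and symbol. Of these, 983 lie on patch contigs and 1362 repeat a symbol, and for a named gene the entry on a chromosome with the highest mean was used.

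Libraries were grouped by cell line, state and treatment as labelled. Replicate numbers were not used as pairs. Each line was fitted alone, with 12 libraries, 4 group means and 8 residual degrees of freedom, and differences between lines with all 24 libraries. Genes were filtered with filterByExpr, scaled by TMM factors, and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as threshold, and genes with an absolute log2 fold change of at least 1 were also counted. CPM values are over the library total without TMM factors, so ratios of CPM means differ from fitted fold changes by the scaling. The questions, tests, lists, alternatives and the rule for named genes were set before the data were examined, except the tests that the closing section names as chosen later.

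Lists of genes (37) were written from general knowledge. Those with at least 5 tested genes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over 280 tests of the 8 main comparisons (secondary comparisons were adjusted as families of their own). An estimated correlation and fry, which asks only whether a list's genes move 1 way on balance, were alternatives. Every adjusted p of a list in the text is from camera unless fry is named. Members were also adjusted within their list alone. Overlaps of calls between comparisons, which share no library, were tested with a one-sided Fisher exact test.

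Named genes were the 5 largest rises and 5 largest falls past the threshold with a mean of at least 10 CPM and no overlap between groups (chance gives 10% of genes no overlap at 3 against 3, and the interaction was excepted), without clone and locus names. EGFR, ERBB2 and ERBB3, up to 3 rising and 3 falling members of each described list with at least 5 CPM, and 8 genes called alike in both lines were added. Of these, examples are printed, and some genes and 1 list are not reported here. SQLE, named by this rule in the 5637 interaction, was also chosen after the results were seen for the parental drug effect and a figure. For a group at 0 counts, a floor of 3 counts per library was used.

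Each step was tested on simulated counts with 200 genes changed. In the 5637 drug comparison (17861 genes) edgeR found 63% of 1.5-fold and 86.7% of 2-fold changes with 7 false calls, and in the 5637 interaction 21% and 78.6%. In OVCAR8 (17849 genes) it found 27.6% and 78.6% for the drug, and 7.14% and 52% for the interaction. Between lines (19806 genes) it found 6.06% and 51%. A simulated list was called in 5637 and OVCAR8 (fixed dispersion 0.01 and 0.02), against 0 of 140 and 0 of 136 other list tests. The preset correlation was not tested.

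Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors, library size only, no filter, a filter of 1 CPM in 3 libraries, robust dispersion, the 6 libraries compared alone, all 24 libraries in 1 fit, replicate number as a block, and leaving out each library in turn. Library totals of 23.8 to 48.5 M counts limit genes of a few counts most. Proteins and the mutation state of ERBB2 were not measured.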

Results

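Messenger RNA of human cancer cell lines was sequenced as 24 libraries, 3 in each of 8 groups. The line 5637 comes from a bladder carcinoma and OVCAR8 from an ovarian carcinoma. Each was present as parental cells and as a neratinib-resistant derivative (NR). Neratinib irreversibly inhibits the kinases of EGFR, ERBB2 (HER2) and ERBB4, and the stated interest of the series was mTORC1 signalling in resistance of HER2-mutant cancers to it. Cells were given neratinib for 24 h, at 600 nM in 5637 and 1 µM in OVCAR8, or control. NR cells were kept free of drug for 1 week before seeding, so NR control libraries describe resistant cells away from the drug. The 3 libraries of a group are dishes in triplicate and may be technical replicates of 1 culture, so every p-value measures the spread between these samples only.

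The count tables held 39786 genes, and library totals ran from 23.8 M in OVCAR8 NR control replicate 2 to 48.5 M in OVCAR8 parental neratinib replicate 2. All 12 libraries of 5637 held 34.9 to 43.3 M counts. Expression is given as CPM, scaled to the library total, as mean ± SD with n = 3 libraries per group, and fold changes as log2 values from edgeR. Within 5637 the first principal component of log2 CPM held 62.1% of the variance and the second 19.4%, and libraries of a group lay together. In OVCAR8 these shares were 37.9% and 26.8%.

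Parental control replicate 2 of OVCAR8 lay apart from its group, at 86 on the second component where the other parental controls lay at 11.5 and 11. Genes longer than 8 kb held 15.4% of its 34.5 M counts, against 22.2% to 23.1% in the other OVCAR8 libraries, and genes under 1 kb held 2.26%, against 1.27% to 1.42%. EGFR (ENSG00000146648.11, hg19 chromosome 7, 55086714 to 55324313) stood at 119 CPM in that library and at 324 and 302 CPM in the other parental controls. The library was kept in the tests, and many counts of genes and list members in OVCAR8 are also given without it. The biological coefficient of variation of OVCAR8 was 13% with it and 4.37% without it, and that of 5637 was 8.03%.

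**Figure D1:**
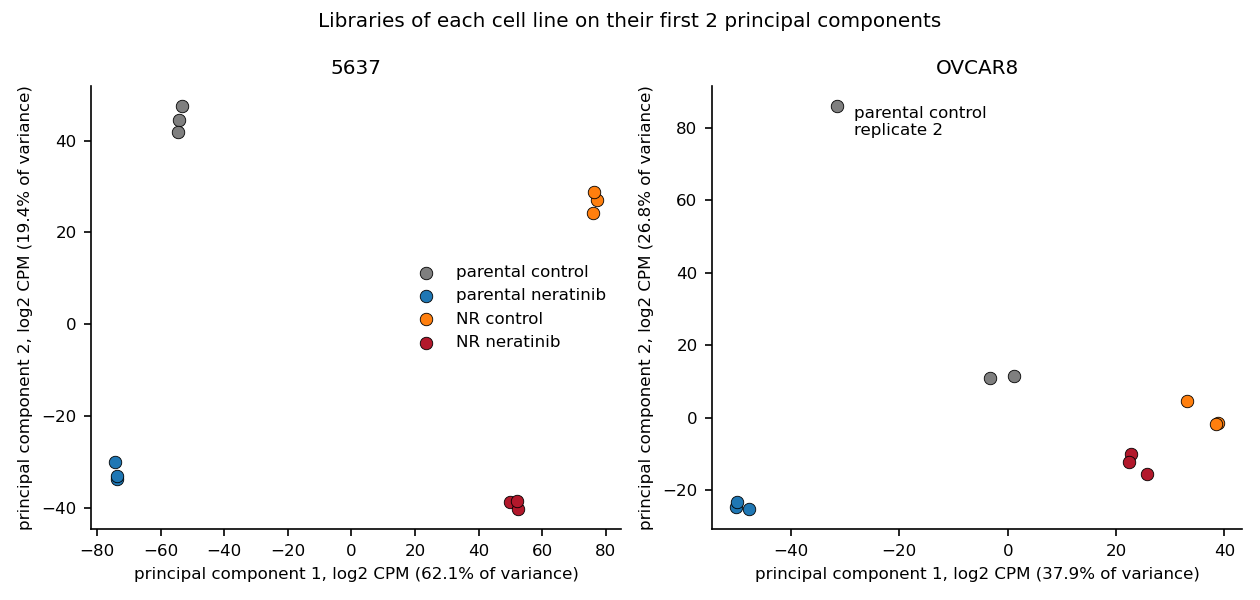
Principal components 1 and 2 of log2 CPM (no units) in 5637, left, and OVCAR8, right, with 1 point per library and colours for the 4 groups of each line. Component 1 holds 62.1% of the variance in 5637 and 37.9% in OVCAR8, where parental control replicate 2 lies at 86 on component 2.

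The effect of neratinib on parental 5637 cells asks what the drug does to cells that have not adapted to it. Genes induced by ERK signalling fell furthest. Genes for cholesterol synthesis, DNA replication, mitosis and ribosome assembly fell with them. Genes that ATF4 drives for amino acid supply rose. Targets of FOXO factors rose by a call that was lost (adjusted p = 0.05 with an estimated correlation). Of 18307 genes tested with edgeR, 4368 rose and 4297 fell, together 47.3% of the genes, and 1718 of them moved at least 2-fold. Scaled by library size alone, rising genes made up 64.2% of the calls in place of 50.4%, and the median log2 fold change of all genes was 0.13 in place of 0.02.

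Of 24 genes of ERK output, whose transcription follows the MAPK cascade below EGFR and RAS, 0 rose, 21 fell and 3 did not pass (median log2 fold change -1.55, camera adjusted p = 6.5e-16). EGR1 (ENSG00000120738.7, hg19 chromosome 5, 137801179 to 137805004), an immediate early transcription factor, fell from 227 ± 62.6 to 0.54 ± 0.171 CPM (log2 -8.81, edgeR adjusted p = 4.4e-12). DUSP6 (ENSG00000139318.7, hg19 chromosome 12, 89741009 to 89747048), the ERK phosphatase, went from 69.5 ± 7.61 to 2.10 ± 0.48 CPM (log2 -5.16, edgeR adjusted p = 1.5e-13). Of 28 inflammatory genes driven by NF-kB, 6 rose and 15 fell (median -0.22, camera adjusted p = 0.0044, but adjusted p = 0.36 with an estimated correlation). Those that fell included the cytokine genes CSF3, CSF2 and IL8, with log2 -3.65, -2.35 and -1.91.

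Sterol synthesis genes under the transcription factor SREBP fell in 21 of 23 cases and rose in 0 (median -1.36, camera adjusted p = 1.3e-16). SQLE, squalene epoxidase, fell from 170 ± 3.62 to 46.2 ± 2.51 CPM. Of 14 fatty acid genes under SREBP, 3 rose and 10 fell (median -0.58, camera adjusted p = 0.002), with the desaturase gene SCD at log2 -1.5. Mixed movement was seen in glycolysis and HIF genes, with 5 rising, 14 falling and 6 of 25 not passing (median -0.26, camera adjusted p = 0.024, but adjusted p = 0.3 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 1030 ± 18.3 to 434 ± 4.75 CPM, whereas VEGFA, an angiogenic factor, rose from 25.2 ± 1.08 to 69.6 ± 4.89 CPM. Pentose phosphate and nucleotide synthesis genes rose in 1 and fell in 16 of 20 cases (median -0.51, camera adjusted p = 2.8e-07). Adjusted over the list alone, the counts of the lists in these paragraphs were the same, except 22 falling for ERK output and 6 rising with 15 falling for glycolysis and HIF.

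Genes of growth and division went down together. In ribosome biogenesis 30 of 33 genes fell and 0 rose (median -0.69, camera adjusted p = 1.5e-16), among them the nucleolar factor LYAR, from 26.2 ± 1.21 to 11.9 ± 0.509 CPM. In DNA replication 31 of 35 fell and 0 rose (median -0.68, camera adjusted p = 1.5e-15), including MCM10, which helps start replication forks, at log2 -1.46, and RRM2, which makes deoxynucleotides, at -1.29. All 30 mitosis genes fell (median -0.85, camera adjusted p = 3.1e-20). CCNB1 (ENSG00000134057.10, hg19 chromosome 5, 68462837 to 68474072), the cyclin that drives entry into mitosis, went from 213 ± 5.31 to 107 ± 5.05 CPM. Of 24 genes of cytoplasmic translation, mostly elongation factors and ribosomal proteins, 14 rose and 0 fell (median 0.19, camera adjusted p = 0.00072, but adjusted p = 0.17 with an estimated correlation), led by EEF2 at log2 0.58. Of 24 nuclear genes of oxidative phosphorylation, 0 rose and 18 fell (median -0.30, camera adjusted p = 9.1e-07, but adjusted p = 0.074 with an estimated correlation), CYC1 among them at log2 -0.61. Of 13 mitochondrial mRNAs, 0 rose and 7 fell (median -0.26, camera adjusted p = 0.031, but adjusted p = 0.71 with an estimated correlation). That call was lost without parental control replicate 3 (0.1) or parental neratinib replicate 1 (0.058) and with library size scaling (0.065). The counts were unchanged when adjusted over the list alone, except 8 falling mitochondrial mRNAs.

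Amino acid genes under ATF4, the effector of the integrated stress response, rose in 33 of 36 cases and fell in 1 (median 1.51, camera adjusted p = 5.4e-25). ASNS (ENSG00000070669.12, hg19 chromosome 7, 97481430 to 97501854), which makes asparagine, rose from 25.3 ± 0.965 to 419 ± 3.77 CPM (log2 3.94, edgeR adjusted p = 4.9e-15). CHAC1 (ENSG00000128965.7, hg19 chromosome 15, 41245160 to 41248710), which degrades glutathione, went from 2.49 ± 0.16 to 78.2 ± 4.43 CPM. The transsulfuration enzyme CBS and the cystine transporter SLC7A11 rose by log2 3.78 and 3.28. ALDH18A1, which starts proline synthesis, was the member that fell, with log2 -0.80. Of 23 FOXO targets, genes held down by AKT, 13 rose and 1 fell (median 0.28, camera adjusted p = 5e-04, but adjusted p = 0.05 with an estimated correlation, a loss). TSC22D3, a leucine zipper gene, rose from 13.4 ± 0.225 to 80.8 ± 2.72 CPM, and IRS1, an adaptor of the insulin receptor, fell by log2 1.35. Lysosome and autophagy genes rose in 16 and fell in 2 of 30 cases (median 0.15, camera adjusted p = 0.0025), with the autophagy receptor SQSTM1 going from 147 ± 2.56 to 425 ± 19.1 CPM. Counts adjusted over the list alone were the same, except 2 falling FOXO targets.

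Receptor tyrosine kinase genes gave no call as a list, with 6 rising and 7 falling of 27 (median -0.15, camera adjusted p = 0.41), the same when adjusted over the list alone. ERBB3 (ENSG00000065361.10, hg19 chromosome 12, 56473641 to 56497289), the kinase-poor partner of ERBB2, rose from 74.8 ± 0.564 to 97.5 ± 1.78 CPM (log2 0.27, edgeR adjusted p = 0.00025). EGFR changed by log2 0.14 (664 ± 17.5 to 785 ± 14.5 CPM, edgeR adjusted p = 0.036). That call was lost without parental control replicates 1, 2 or 3 (0.12, 0.055 and 0.11) and without parental neratinib replicates 1, 2 or 3 (0.055, 0.13 and 0.087), and with the replicate block (0.054). ERBB2 (ENSG00000141736.9, hg19 chromosome 17, 37844167 to 37886679) changed by log2 0.20 (268 ± 7.25 to 331 ± 9.14 CPM, edgeR adjusted p = 0.035), and the call was lost without parental control replicates 1, 2 or 3 (0.051, 0.089 and 0.12) and without parental neratinib replicates 1 or 2 (0.09 and 0.11). The mTORC1 machinery list, the genes of the complex and its regulators, gave no call (6 rising and 8 falling of 30, or 6 and 9 adjusted over the list alone, camera adjusted p = 0.68), and its median of -0.12 and mean of 0.03 differed in sign.

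**Figure D2:**
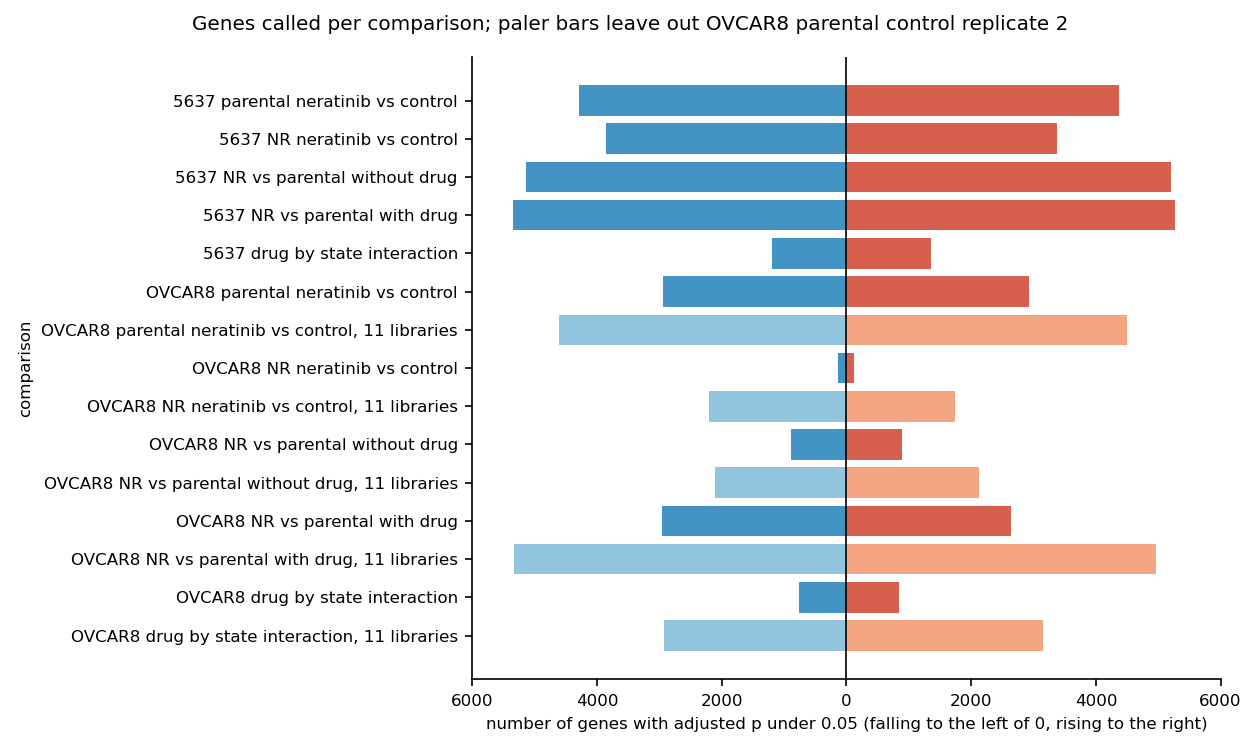
Number of genes that rose (bars to the right) and fell (bars to the left) in each comparison by edgeR, in genes, for 5637 and OVCAR8. Paler bars count the same OVCAR8 comparisons without parental control replicate 2, where the drug effect in NR cells goes from 116 rising and 135 falling genes to 1740 and 2210.

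The same question in parental OVCAR8 cells met a higher dose and noisier controls. Amino acid genes under ATF4 rose there too, and genes for cholesterol synthesis, DNA replication and mitosis fell. ERK output genes fell by less than in 5637, a fall whose call was lost (adjusted p = 0.13 with an estimated correlation), and inflammatory genes rose. Of 18072 genes tested with edgeR, 2922 rose and 2946 fell, 32.5% of the genes, and 1089 moved at least 2-fold. Without parental control replicate 2 the counts were 4506, 4611 and 1207. Scaled by library size alone, rising genes made up 62.6% of the calls in place of 49.8%, and the median log2 fold change of all genes was 0.11 in place of 0.01.

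ERK output genes fell in 12 of 24 cases and rose in 0 (median -0.34, camera adjusted p = 0.00019, but adjusted p = 0.13 with an estimated correlation). ETV4, an ETS transcription factor, went from 53.2 ± 1.32 to 19.5 ± 1.19 CPM (log2 -1.55, edgeR adjusted p = 2.6e-07). ATF4 targets rose in 35 of 37 cases and fell in 1 (median 1.27, camera adjusted p = 1e-29). INHBE (ENSG00000139269.2, hg19 chromosome 12, 57846106 to 57853063), an activin subunit, had the largest rise, from 1.40 ± 0.277 to 35.9 ± 1.55 CPM (log2 4.59, edgeR adjusted p = 1.6e-08). DDIT4 (ENSG00000168209.4, hg19 chromosome 10, 74033678 to 74035794), a stress-induced inhibitor of mTORC1, rose by log2 3.54, and CHAC1 and SLC7A11 by 3.29 and 3.15. FOXO targets rose in 13 of 23 cases and fell in 0 (median 0.35, camera adjusted p = 6.4e-06). Of 24 NF-kB genes, 14 rose and 2 fell (median 0.49, camera adjusted p = 8e-05). Within each list alone, ATF4 targets had 36 rising, FOXO targets 16 rising, and NF-kB genes 15 rising with 3 falling, while ERK output was the same.

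Sterol genes fell in 19 of 23 cases and rose in 1 (median -1.13, camera adjusted p = 6.6e-15). INSIG1, which holds SREBP in the endoplasmic reticulum, fell from 43.3 ± 6.29 to 9.58 ± 0.189 CPM. TM7SF2, a sterol reductase, rose by log2 0.87. Of 14 fatty acid genes, 1 rose and 7 fell (median -0.29, camera adjusted p = 0.018, but adjusted p = 0.32 with an estimated correlation), with SCD at log2 -1.27. Glycolysis and HIF genes rose in 4 and fell in 16 of 24 cases (median -0.42, camera adjusted p = 0.00011, but adjusted p = 0.063 with an estimated correlation). VEGFA rose from 17.3 ± 0.474 to 67.8 ± 6.11 CPM, and ADM, the vasodilator peptide adrenomedullin, fell from 58.1 ± 9.33 to 14.2 ± 1.09 CPM. Pentose phosphate and nucleotide genes fell in 15 of 21 cases and rose in 0 (median -0.41, camera adjusted p = 4.1e-05, but adjusted p = 0.05 with an estimated correlation, a loss). When adjusted over the list alone, fatty acid genes had 2 rising and nucleotide genes 1 rising, and the other counts were the same. Leaving out parental control replicate 2, rising and falling genes numbered 0 and 14 for ERK output, 36 and 1 for ATF4, 14 and 1 for FOXO, 16 and 3 for NF-kB, 1 and 20 for sterol, 3 and 9 for fatty acid, 4 and 18 for glycolysis and 3 and 15 for nucleotide genes.

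In DNA replication 32 of 35 genes fell and 0 rose (median -0.73, camera adjusted p = 4.8e-18), and in mitosis 27 of 30 fell and 0 rose (median -0.63, camera adjusted p = 1.1e-15). CDC6, which licenses replication origins, went from 118 ± 6.72 to 59.6 ± 1.98 CPM, and CCNB1 from 277 ± 35.5 to 159 ± 3.12 CPM. Ribosome biogenesis genes fell in 25 of 33 cases and rose in 0 (median -0.43, camera adjusted p = 8.2e-10), with LYAR at log2 -1.12. Lysosome and autophagy genes rose in 7 and fell in 1 of 29 cases (median 0.19, camera adjusted p = 0.028, but adjusted p = 0.33 with an estimated correlation), and the call was lost without parental control replicate 1 (0.087). SQSTM1 and ULK1, a kinase that starts autophagy, rose by log2 1 and 0.81. Cytoplasmic translation gave no call, with 5 of 24 genes rising and 0 falling (median 0.07, camera adjusted p = 0.15), but 22 rose and 0 fell without parental control replicate 2 (median 0.34, camera adjusted p = 1.7e-11). Oxidative phosphorylation genes fell in 13 of 24 cases and rose in 0 (median -0.48, camera adjusted p = 7.6e-06, but adjusted p = 0.5 with an estimated correlation), with NDUFB8, a subunit of complex I, at log2 -1.09. Without parental control replicate 2 that median was -0.19 (16 falling, camera adjusted p = 8.4e-05) and NDUFB8 stood at -0.67, so the size of this fall rests largely on that library. Mitochondrial mRNAs fell in 5 of 13 cases and rose in 0 (median -0.22, camera adjusted p = 0.038, but adjusted p = 0.56 with an estimated correlation), a call lost without parental control replicate 3 (0.1) or parental neratinib replicate 3 (0.055) and with library size scaling (0.06). Counts adjusted over the list alone differed for ribosome biogenesis (26 falling), translation (4 rising), oxidative phosphorylation (18 falling) and mitochondrial mRNAs (6 falling). With parental control replicate 2 left out, rising and falling genes were 1 and 34 for replication, 0 and 30 for mitosis, 1 and 31 for ribosome biogenesis and 15 and 2 for lysosome genes.

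Receptor tyrosine kinase genes gave no call (8 rising and 5 falling of 21, the same adjusted over the list alone, camera adjusted p = 0.32). ERBB3 rose from 142 ± 21.2 to 213 ± 3.28 CPM (log2 0.49, edgeR adjusted p = 0.00069, and 3.1e-07 without parental control replicate 2). EGFR (log2 0.39, edgeR adjusted p = 0.23) and ERBB2 (log2 0.07, edgeR adjusted p = 0.42) gave no call with that library, nor without it (log2 0.08 and 0.08, edgeR adjusted p = 0.11 and 0.16). The mTORC1 machinery list gave no call either (6 rising and 4 falling of 32, the same adjusted over the list alone, median 0.03, camera adjusted p = 0.73). Receptors had 10 rising and 7 falling and mTORC1 genes 8 and 8 without parental control replicate 2.

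Whether the drug acted alike in both lines was asked by overlap and by the difference of the effects. Of 16246 genes tested in both, 1692 rose in both lines where 653 would by chance, and 1903 fell in both where 695 would. Opposite calls numbered 105 and 135. Without OVCAR8 parental control replicate 2, 2306 rose and 2534 fell in both, where chance gives 1010 and 1080. In a fit of all 24 libraries over 20250 genes, the effect in OVCAR8 minus that in 5637 was called as higher in 1105 genes and lower in 978. Without OVCAR8 parental control replicate 2 these counts were 2017 and 1852, and the lower count was 602 without 5637 parental control replicate 1 and 645 without 5637 parental control replicate 2. Line and dose cannot be separated here.

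ERK output genes differed most as a list, with 19 of 24 less lowered in OVCAR8 and 0 more (median difference 1.24, camera adjusted p = 2.8e-30). NF-kB genes were higher by this measure in 15 and lower in 2 of 28 cases (median 0.70, camera adjusted p = 4e-11). Sterol genes were higher in 10 and lower in 1 of 23 (median 0.35, camera adjusted p = 5.2e-06), and mitosis genes in 3 and 0 of 30 (median 0.19, camera adjusted p = 8e-05, but adjusted p = 0.083 with an estimated correlation). With list-wise adjustment, the pairs of counts in this order were 21 and 0, 17 and 2, 11 and 2, and 4 and 0.

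NR and parental 5637 cells without drug were compared to ask how NR cells differed once the drug was gone. Inflammatory cytokine genes and genes of glycolysis and hypoxia stood higher in NR cells. ERK output genes also stood higher and lists of squamous and urothelial genes lower, but these calls were lost (adjusted p = 0.075, 0.069 and 0.19 with an estimated correlation). Sterol, mitosis and DNA replication genes gave no call. Of 18307 genes tested with edgeR, 5207 rose and 5132 fell, 56.5% of the genes, and 3220 differed at least 2-fold.

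The largest differences were between near absence and clear expression. OSTN (ENSG00000188729.2, hg19 chromosome 3, 190917030 to 190983404), a secreted peptide of muscle and bone, had 0 counts in parental controls and 29.9 ± 5.73 CPM in NR controls, a difference of at least 410-fold at a floor of 0.0731 CPM. PLXDC2 (ENSG00000120594.12, hg19 chromosome 10, 20105168 to 20578785), a membrane protein, had 0 counts in NR controls and 47.3 ± 1.69 CPM in parental controls, at least 594-fold. Ratios with 95% intervals were 912 (419 to 2490) for ROBO4 and 215 (126 to 404) for DLL4, a guidance receptor and a Notch ligand of blood vessels, which rose. The ratio was 1030 (616 to 1890) for KRT13, which fell. These floors and intervals cover counting error only.

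NF-kB inflammatory genes rose in 24 and fell in 2 of 28 cases (median 1.40, camera adjusted p = 1.2e-12). IL6 (ENSG00000136244.7, hg19 chromosome 7, 22765503 to 22771621) rose from 0.347 ± 0.0865 to 14.8 ± 0.835 CPM (log2 5.38, edgeR adjusted p = 4.4e-13) and CSF3 from 10.6 ± 0.729 to 398 ± 49.4 CPM. NFKBIA, the inhibitor of NF-kB, fell by log2 0.50. Genes of glycolysis and HIF rose in 21 and fell in 2 of 25 cases (median 1.04, camera adjusted p = 3e-09). BNIP3, a mitophagy receptor, went from 8.34 ± 0.537 to 81.6 ± 1.55 CPM, and VEGFA from 25.2 ± 1.08 to 131 ± 7.66 CPM, while the glucose transporter SLC2A1 fell by log2 0.37. ERK output genes rose in 17 and fell in 2 of 24 cases (median 0.97, camera adjusted p = 7.3e-06, but adjusted p = 0.075 with an estimated correlation). SPRY4, a feedback inhibitor, ETV4 and the phosphatase DUSP4 rose by log2 2.68, 2.61 and 2.46, and EGR1 fell from 227 ± 62.6 to 47.8 ± 10.8 CPM. Of 30 lysosome and autophagy genes 13 rose and 4 fell (median 0.22, camera adjusted p = 0.033, but adjusted p = 0.088 with an estimated correlation), SQSTM1 by log2 1.2 and ULK1 by -0.69. The counts were the same adjusted over the list alone, except 3 falling NF-kB genes.

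Markers of epithelial type mostly fell. Basal and squamous genes rose in 5 and fell in 21 of 28 cases (median -2.27, camera adjusted p = 1.3e-06, but adjusted p = 0.069 with an estimated correlation). PKP1, a desmosome plaque protein, went from 181 ± 4.30 to 4.42 ± 0.451 CPM, and the keratin KRT6A from 363 ± 5.25 to 11.9 ± 0.747 CPM. Urothelial luminal genes rose in 4 and fell in 8 of 13 cases (median -1.89, camera adjusted p = 0.019, but adjusted p = 0.19 with an estimated correlation). KRT13 (ENSG00000171401.10, hg19 chromosome 17, 39657233 to 39661957), a keratin of the urothelium, went from 128 ± 10.4 to 0.121 ± 0.0555 CPM, and the uroplakin UPK3B from 84 ± 5.23 to 2.97 ± 0.212 CPM. Of 27 epithelial genes 6 rose and 18 fell (median -0.37, camera adjusted p = 0.0025, but adjusted p = 0.17 with an estimated correlation). FOXO targets rose in 4 and fell in 15 of 23 cases (median -0.49, camera adjusted p = 0.00093, but adjusted p = 0.06 with an estimated correlation). Translation genes rose in 2 and fell in 17 of 24 cases (median -0.43, camera adjusted p = 4.2e-05, but adjusted p = 0.1 with an estimated correlation), EEF2 by log2 0.89. Mesenchymal genes gave no call (12 rising and 9 falling of 24, camera adjusted p = 0.77), with a median of 0.23 and a mean of -0.50. Adjusting by list, the counts were the same, apart from 10 falling mesenchymal genes.

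Other core lists gave no call by camera. They were ATF4 targets (16 rising and 10 falling of 36, camera adjusted p = 0.54), sterol genes (9 and 5 of 23, 0.6), ribosome biogenesis (14 and 5 of 33, 0.17), DNA replication (18 and 10 of 35, 0.16), mitosis (7 and 11 of 30, 0.15), receptor tyrosine kinases (10 and 12 of 27, 0.73) and mTORC1 machinery (10 and 9 of 30, 0.81). The counts were the same adjusted over the list alone, except 11 falling ATF4 targets and 10 falling mTORC1 genes. The receptor list had a median of -0.21, a mean of 0.37 and a downward test. ERBB2 went from 268 ± 7.25 to 156 ± 8.05 CPM (log2 -0.79, edgeR adjusted p = 1.8e-07) and ERBB3 from 74.8 ± 0.564 to 41.6 ± 0.606 CPM (log2 -0.86, edgeR adjusted p = 7.2e-10). EGFR rose by log2 0.25 (664 ± 17.5 to 800 ± 41.7 CPM, edgeR adjusted p = 0.00044).

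The same comparison in OVCAR8, also of 1 derivative, cannot tell resistance from drift. Inflammatory and glycolysis genes stood higher in NR cells here too. ERK output genes stood higher and epithelial genes lower, but these calls were lost (adjusted p = 0.05 and 0.05 with an estimated correlation). Far fewer genes differed than in 5637. Of 18072 genes tested with edgeR, 892 rose and 887 fell, 9.84% of the genes, and 497 differed at least 2-fold, against 2118, 2107 and 536 without parental control replicate 2. Without any 1 of the NR controls 503 to 546 genes rose and 490 to 576 fell, and 1446 fell without parental control replicate 1.

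GREM1 (ENSG00000166923.6, hg19 chromosome 15, 33010175 to 33026870), a secreted BMP antagonist, rose from 2.96 ± 0.641 to 57.5 ± 3.23 CPM (log2 4.24, edgeR adjusted p = 4.2e-09). BNC1, a zinc finger gene of keratinocytes and germ cells, fell from 49.7 ± 20.4 to 4.59 ± 0.353 CPM. NF-kB genes rose in 12 and fell in 1 of 24 cases (median 0.61, camera adjusted p = 4.5e-07), IL1A from 1.30 ± 0.316 to 15.2 ± 1.00 CPM. Glycolysis and HIF genes rose in 14 and fell in 1 of 24 cases (median 0.36, camera adjusted p = 3.2e-08), with hexokinase gene HK2 at log2 1.17 and BNIP3 at 0.95. ERK output genes rose in 14 and fell in 3 of 24 cases (median 0.51, camera adjusted p = 1.4e-07, but adjusted p = 0.05 with an estimated correlation, a loss). PHLDA1 rose from 33.7 ± 2.49 to 82.2 ± 3.49 CPM and EGR1 by log2 1.61, and EMP1, a membrane protein, fell by 1.23. Adjusted over the list alone, NF-kB genes had 14 rising with 4 falling and glycolysis genes 16 with 2, while ERK output was the same. These counts without parental control replicate 2 were 14 and 3, 19 and 1, and 14 and 3.

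Epithelial genes fell in 8 of 23 cases and rose in 0 (median -0.39, camera adjusted p = 9.6e-05, but adjusted p = 0.05 with an estimated correlation, a loss). The keratin KRT7 went from 1280 ± 240 to 434 ± 20 CPM. Basal and squamous genes rose in 1 and fell in 5 of 15 cases (median -0.61, camera adjusted p = 0.027, but adjusted p = 0.18 with an estimated correlation), a call lost without parental control replicate 3 (0.056), with the integrin ITGB4 at log2 -1.26. Mullerian and ovarian genes rose in 1 and fell in 3 of 9 cases (median -0.31, camera adjusted p = 0.02, but adjusted p = 0.17 with an estimated correlation), among them PAX8, a lineage factor of ovarian carcinoma, at log2 -0.92. That call was lost without parental control replicate 2 (0.12), NR control replicate 1 (0.052) or parental control replicate 3 (0.052). DNA replication genes fell in 2 of 35 cases and rose in 0 (median -0.14, camera adjusted p = 0.014, but adjusted p = 0.36 with an estimated correlation). Ribosome biogenesis genes rose in 4 of 33 cases and fell in 0 (median 0.01, camera adjusted p = 0.038, but adjusted p = 0.4 with an estimated correlation). Without parental control replicate 2, 15 of them rose (camera adjusted p = 7.9e-07), but the call was lost without NR control replicates 1 or 3 (0.085 and 0.08) and parental control replicates 1 or 3 (0.1 and 0.29). Oxidative phosphorylation genes passed in 0 of 24 cases by edgeR (6 at an unadjusted p under 0.05, 0 by DESeq2), with a median of -0.27 and a camera adjusted p = 0.011, but adjusted p = 0.71 with an estimated correlation. Without parental control replicate 2 their direction was reversed (median 0.01, camera adjusted p = 0.84). Counts adjusted over the list alone were 9 falling epithelial genes, 3 rising with 8 falling basal genes, 4 falling ovarian genes, 0 DNA replication genes, 7 rising ribosome genes and 0 oxidative phosphorylation genes. Leaving out parental control replicate 2, the rising and falling genes were 0 and 10 for epithelial, 4 and 7 for basal (median -0.38), 2 and 5 for ovarian and 2 and 8 for DNA replication genes (median -0.06).

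Other lists gave no call with parental control replicate 2 kept. They were FOXO targets (3 rising and 3 falling of 23, camera adjusted p = 0.84), ATF4 targets (3 and 1 of 37, 0.72), sterol genes (1 and 2 of 23, 0.38), lysosome and autophagy (1 and 2 of 29, 0.18), mitosis (0 and 1 of 30, 0.9), receptor tyrosine kinases (4 and 5 of 21, 0.29), mTORC1 machinery (0 and 1 of 32, 0.47) and translation (0 of 24 passing, 1 at an unadjusted p under 0.05 and 1 by DESeq2, 0.28). Within each list alone, FOXO targets had 5 and 5, sterol genes 3 and 5, and receptors 8 and 5, with the others the same. The counts without parental control replicate 2 were 6 and 7 for FOXO, 6 and 9 for ATF4, 4 and 7 for sterol, 4 and 5 for lysosome, 4 and 5 for mitosis, 8 and 6 for receptor and 4 and 5 for mTORC1 genes. FOXO targets had a median of -0.09 and a mean of 0.04. Translation had a median of -0.18, and without parental control replicate 2 it was called upward (9 rising and 0 falling, median 0.08, camera adjusted p = 8.7e-05). ERBB3 went from 142 ± 21.2 to 100 ± 3.97 CPM (log2 -0.54, edgeR adjusted p = 0.001, and 3.8e-09 without parental control replicate 2). ERBB2 went from 133 ± 6.69 to 115 ± 2.61 CPM (log2 -0.25, edgeR adjusted p = 0.023), a call lost without NR control replicates 1, 2 or 3 (0.059, 0.095 and 0.095) and with the replicate block (0.05). EGFR gave no call (log2 0.39, edgeR adjusted p = 0.29, and log2 0.08 with 0.16 without parental control replicate 2).

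Overlap between the lines in this comparison was modest. Of the genes tested in both, 392 rose in both where 222 would by chance (one-sided Fisher exact p = 6.5e-40) and 291 fell in both where 224 would (p = 8.3e-08 by the same exact test). Genes rising in 5637 and falling in OVCAR8, or the reverse, numbered 260 and 179, where chance gives 222 and 224, and the first of these had p = 0.0015 by the exact test. Genes are not independent, so these p-values are descriptive. Without OVCAR8 parental control replicate 2, 844 rose and 743 fell in both, where chance gives 550 and 562. Among the genes called alike, IL1B (ENSG00000125538.7, hg19 chromosome 2, 113587328 to 113594480), an inflammatory cytokine, rose by log2 2.74 in 5637 and 2.57 in OVCAR8, and STC2 (ENSG00000113739.6, hg19 chromosome 5, 172741716 to 172756506), a secreted glycoprotein of the stress response, by 3.15 and 1.72.

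The difference between NR and parental cells in OVCAR8 minus that in 5637 was called as higher in 3003 and lower in 3660 of 20250 genes, and in 3879 and 4257 without OVCAR8 parental control replicate 2. Genes of glycolysis and HIF were higher in 3 and lower in 17 of 25 cases (median -0.61, camera adjusted p = 6.4e-06). NF-kB genes were higher in 1 and lower in 16 of 28 (median -1.15, camera adjusted p = 7.3e-05, but adjusted p = 0.055 with an estimated correlation). With list-wise adjustment, 18 glycolysis and 17 NF-kB genes were lower.

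**Figure D3:**
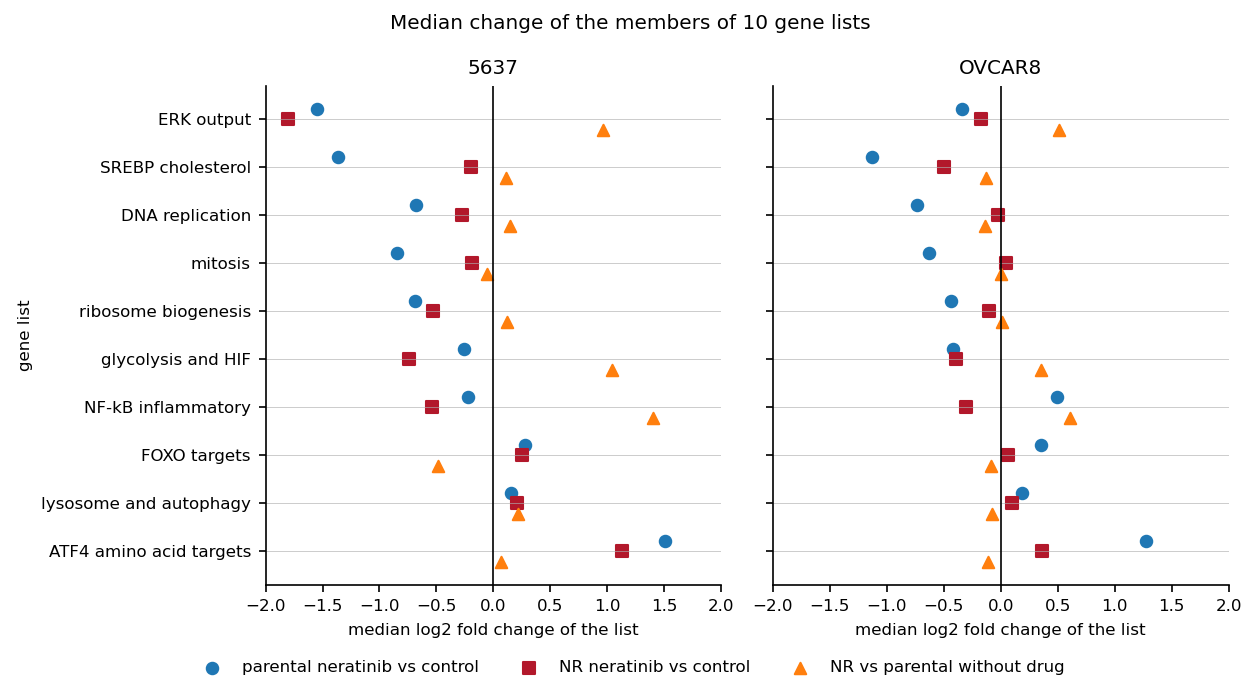
Median log2 fold change of 10 gene lists for the drug effect in parental cells (circles), the drug effect in NR cells (squares) and NR against parental cells without drug (triangles), with 5637 left and OVCAR8 right. In 5637 the median for mitosis under the drug is -0.85 in parental and -0.19 in NR cells, while that for ERK output is -1.55 and -1.80.

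The drug effect in NR 5637 cells, back on neratinib after a week without it, asks which responses resistant cells keep. ERK output genes fell, with no call for a difference from parental cells, and ATF4 targets rose, but by less than in parental cells. Falls of sterol and mitosis genes were much smaller. Of 18307 genes tested with edgeR, 3372 rose and 3858 fell, 39.5% of the genes, and 1379 moved at least 2-fold. Scaled by library size alone, rising genes made up 67.4% of the calls in place of 46.6%, and the median log2 fold change of all genes was 0.12 in place of -0.002. In both kinds of 5637 cell 2321 genes rose and 2677 fell under the drug, where chance gives 805 and 906, and 114 and 107 had opposite calls.

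ERK output genes fell in 23 of 24 cases and rose in 0 (median -1.80, camera adjusted p = 4.5e-24). EGR1 went from 47.8 ± 10.8 to 0.425 ± 0.048 CPM, SPRY4 from 63.8 ± 3.62 to 1.74 ± 0.298 CPM, DUSP6 from 131 ± 2.90 to 5.12 ± 0.402 CPM and ETV4 from 170 ± 10.5 to 11.9 ± 0.658 CPM. ATF4 targets rose in 32 and fell in 3 of 36 cases (median 1.13, camera adjusted p = 1.1e-21). ASNS went from 21.8 ± 1.38 to 282 ± 16.2 CPM (log2 3.57, edgeR adjusted p = 2e-14), CBS rose by log2 3.31, and STC2 fell by 0.56. FOXO targets rose in 11 and fell in 2 of 23 cases (median 0.25, camera adjusted p = 0.0043, but adjusted p = 0.088 with an estimated correlation). NF-kB genes rose in 5 and fell in 18 of 28 cases (median -0.54, or -0.44 with genes at their detection bound, camera adjusted p = 4.3e-06, but adjusted p = 0.15 with an estimated correlation). CSF3 went from 398 ± 49.4 to 52.4 ± 7.76 CPM. Lysosome genes rose in 14 and fell in 3 of 30 cases (median 0.21, camera adjusted p = 0.0052). Adjusting by list, ATF4 targets and lysosome genes had 4 falling, and the other counts were the same.

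Glycolysis and HIF genes rose in 1 and fell in 22 of 25 cases (median -0.74, camera adjusted p = 8.5e-13), with BNIP3 going from 81.6 ± 1.55 to 32.4 ± 1.45 CPM and LDHA from 2760 ± 171 to 1230 ± 93.2 CPM. Ribosome biogenesis genes fell in 32 of 33 cases and rose in 0 (median -0.53, camera adjusted p = 3.4e-16). Sterol genes fell in 9 of 23 cases and rose in 0 (median -0.20, camera adjusted p = 0.0044, but adjusted p = 0.069 with an estimated correlation), HMGCS1, an early enzyme of sterol synthesis, by log2 0.52. Fatty acid genes gave no call (2 rising and 5 falling of 14, camera adjusted p = 0.55). DNA replication genes rose in 1 and fell in 21 of 35 cases (median -0.27, camera adjusted p = 4.5e-06, but adjusted p = 0.067 with an estimated correlation), RRM2 by log2 0.75. Mitosis genes fell in 16 of 30 cases and rose in 0 (median -0.19, camera adjusted p = 0.002, but adjusted p = 0.33 with an estimated correlation, and 0.059 with library size scaling). Nucleotide synthesis genes rose in 3 and fell in 14 of 20 cases (median -0.34, camera adjusted p = 3e-04, but adjusted p = 0.082 with an estimated correlation). Oxidative phosphorylation genes fell in 9 of 24 cases and rose in 0 (median -0.12, camera adjusted p = 0.016, but adjusted p = 0.36 with an estimated correlation, and 0.25 with library size scaling). The counts adjusted over the list alone were the same, except 2 rising with 22 falling for DNA replication and 15 falling for nucleotide synthesis.

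Translation (2 rising and 4 falling of 24, camera adjusted p = 0.76), receptor tyrosine kinases (7 and 6 of 27, 0.98) and mTORC1 machinery (8 and 10 of 30, 0.95) gave no call. These counts were 2 and 3, 7 and 6, and 9 and 10 adjusted over the list alone, and the receptor list had a median of -0.03 with an upward test. ERBB2 rose from 156 ± 8.05 to 217 ± 22.5 CPM (log2 0.35, edgeR adjusted p = 0.0014) and ERBB3 from 41.6 ± 0.606 to 61.9 ± 0.65 CPM (log2 0.45, edgeR adjusted p = 4.2e-06). EGFR gave no call (log2 -0.02, edgeR adjusted p = 0.79).

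Whether the drug response of NR 5637 cells differed from that of parental cells was tested by the interaction. It was above 0 in 1352 genes and below 0 in 1187 by edgeR, together 13.9% of the genes, with 507 at least 2-fold. Values above 0 mean a smaller fall or a larger rise in NR cells. All 30 mitosis genes were above 0 (median 0.70, camera adjusted p = 2.9e-30). CCNB1 fell from 213 ± 5.31 to 107 ± 5.05 CPM in parental cells and stood at 148 ± 2.42 and 138 ± 9.35 CPM in NR cells (interaction 0.88, edgeR adjusted p = 2.8e-06). DNA replication genes were above 0 in 25 and below in 0 of 35 cases (median 0.40, camera adjusted p = 3.4e-16), CDC6 at 0.70. Sterol genes were above 0 in 19 and below in 0 of 23 cases (median 1.11, camera adjusted p = 2.2e-29). SQLE had 1.89 (edgeR adjusted p = 2.6e-09), at 167 ± 9.75 and 171 ± 14.9 CPM in NR cells. Adjusted over the list alone, DNA replication had 29 and 1, sterol genes 20 and 0, and mitosis was the same.

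ATF4 targets were above 0 in 1 and below in 20 of 36 cases (median -0.32, camera adjusted p = 1.6e-11). STC2, which rose in parental cells and fell in NR cells, had -2.60 and CHAC1 -2.45. Genes of glycolysis and HIF were above 0 in 1 and below in 10 of 25 (median -0.27, camera adjusted p = 1.3e-05, but adjusted p = 0.05 with an estimated correlation, a loss), VEGFA at -2.21. Translation genes were below 0 in 8 of 24 and above in 0 (median -0.19, camera adjusted p = 9.1e-07, but adjusted p = 0.06 with an estimated correlation). Within each list alone, ATF4 targets had 2 and 23, glycolysis 2 and 12, and translation 10 below.

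ERK output gave no interaction call (4 above and 10 below of 24, median -0.39, camera adjusted p = 0.056), but it did without NR control replicate 1 (0.035), NR control replicate 2 (0.05), parental control replicate 1 (0.048) or parental neratinib replicate 2 (0.047). CCND1, cyclin D1, had -0.90 and FOSL1, a subunit of AP-1, 1.27. FOXO targets (1 and 7 of 23, camera adjusted p = 0.18), lysosome genes (1 and 6 of 30, 0.25), receptor tyrosine kinases (3 and 0 of 27, 0.16), NF-kB genes (6 and 6 of 28, 0.48) and mTORC1 machinery (2 and 2 of 30, 0.86) gave no call. With list-wise adjustment, ERK output had 5 and 10, FOXO 2 and 7, NF-kB 7 and 10 and mTORC1 machinery 1 and 2. EGFR, ERBB2 and ERBB3 gave no call (edgeR adjusted p = 0.18, 0.4 and 0.12). MPPED2, at 3.59, stood at 0.0538 ± 0.0277 and 0.631 ± 0.271 CPM in NR cells, so its value rests on few counts.

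**Figure D4:**
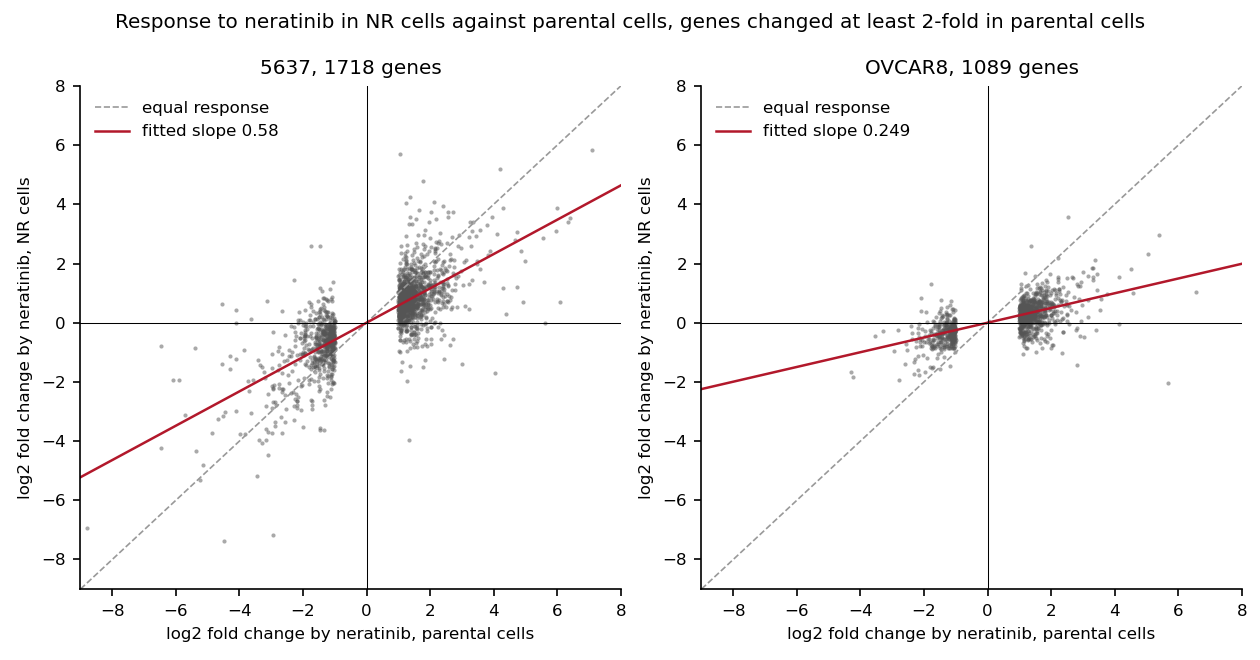
Drug effect in NR cells (vertical axis, log2 fold change) against that in parental cells (horizontal axis, log2 fold change) for genes that moved at least 2-fold in parental cells, 1 point per gene, with 5637 left and OVCAR8 right. Solid lines are fitted slopes of 0.58 over 1718 genes and 0.249 over 1089 genes, and dashed lines mark equal effects.

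NR OVCAR8 cells put back on neratinib were asked the same question. Few genes passed the test. ATF4 targets rose as a list, and sterol and glycolysis genes fell. Of 18072 genes tested with edgeR, 116 rose and 135 fell, 1.39% of the genes, and 33 moved at least 2-fold, against 1740, 2210 and 139 without parental control replicate 2, which lies outside both groups compared but enters the shared dispersion. Without any 1 of the 6 NR libraries 21 to 36 genes rose and 22 to 42 fell. A fit of the 6 libraries of the comparison alone gave 1633 rising and 2008 falling genes. Genes called in both kinds of OVCAR8 cell numbered 110 rising and 93 falling, where chance gives 18.8 and 22 (one-sided Fisher exact p = 1.7e-79 and 2e-42), with 1 and 1 in opposite directions. Without parental control replicate 2 they numbered 1131 and 1241, where chance gives 423 and 550.

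ATF4 targets rose in 16 of 37 cases and fell in 0 (median 0.36, camera adjusted p = 5.3e-33). ASNS went from 40.8 ± 3.52 to 136 ± 0.738 CPM (log2 1.72, edgeR adjusted p = 0.00024), and SLC7A11 rose by log2 1.58. Sterol genes fell in 8 of 23 cases and rose in 0 (median -0.50, camera adjusted p = 1.8e-14), INSIG1 from 46.3 ± 2.97 to 20.3 ± 1.59 CPM and HMGCS1 from 104 ± 9.35 to 58.2 ± 2.43 CPM. Glycolysis and HIF genes rose in 1 and fell in 12 of 24 cases (median -0.40, camera adjusted p = 6.3e-18), HK2 from 35.1 ± 1.19 to 18.9 ± 0.606 CPM. NF-kB genes fell in 3 of 24 cases and rose in 0 (median -0.31, camera adjusted p = 9.6e-05). ERK output genes fell in 3 of 24 cases and rose in 0 (median -0.17, camera adjusted p = 8.5e-06, but adjusted p = 0.08 with an estimated correlation). Fatty acid genes fell in 2 of 14 and rose in 0 (median -0.20, camera adjusted p = 3e-04, but adjusted p = 0.13 with an estimated correlation), and ribosome biogenesis genes passed in 0 of 33 cases by edgeR (6 at an unadjusted p under 0.05, 3 by DESeq2, median -0.10, camera adjusted p = 0.00024, but adjusted p = 0.15 with an estimated correlation). Adjusting by list, counts in this order were 30 and 0, 1 and 16, 1 and 17, 0 and 8, 1 and 8, 0 and 3, and 0 and 2. They were 33 and 1, 1 and 16, 1 and 19, 2 and 12, 2 and 13, 0 and 8, and 0 and 14 without parental control replicate 2.

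No gene passed by edgeR in DNA replication (35 genes, camera adjusted p = 0.3), mitosis (30, 0.24), FOXO targets (23, 0.57), lysosome genes (29, 0.083), translation (24, 0.23), receptor tyrosine kinases (21, 0.47) or mTORC1 machinery (32, 0.41). At an unadjusted p under 0.05 these lists had 2, 1, 5, 6, 0, 4 and 4 genes, and DESeq2 called 0, 0, 1, 3, 0, 1 and 3. Adjusted over the list alone, 1 receptor gene fell and 3 mTORC1 genes rose. Lysosome genes were called with library size scaling (0.044), without NR neratinib replicate 2 (0.033) and without parental control replicate 2 (0.0063, 9 rising and 3 falling), and translation without the latter (0.0092, 7 and 2). Mitosis had 2 rising and 1 falling, DNA replication 0 and 6, FOXO targets 3 and 3, receptors 2 and 5 and mTORC1 machinery 5 and 3 without parental control replicate 2. EGFR, ERBB2 and ERBB3 gave no call (edgeR adjusted p = 0.89, 0.7 and 0.73), though EGFR passed without parental control replicate 2 (log2 0.12, edgeR adjusted p = 0.018).

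Interaction in OVCAR8 was above 0 in 835 genes and below 0 in 760 by edgeR, together 8.83%, with 346 at least 2-fold, against 3157, 2919 and 607 without parental control replicate 2. Scaled by library size alone, 40.5% of the calls were above 0 in place of 52.4%. Without any 1 of the NR libraries or of the parental neratinib libraries the counts were 409 to 497 above and 375 to 497 below, and the 2-fold count was 227 without NR control replicate 1, 226 without NR neratinib replicate 1 and 221 without parental neratinib replicate 2. Over genes that moved at least 2-fold in parental cells, the slope of the NR response on the parental response was 0.249 in OVCAR8 (1089 genes, 82.4% in the same direction) and 0.58 in 5637 (1718 genes, 89.8%), and 0.236 in OVCAR8 without that library.

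Mitosis genes were above 0 in 21 and below in 0 of 30 cases (median 0.68, camera adjusted p = 3.6e-22) and DNA replication genes in 21 and 0 of 35 (median 0.70, camera adjusted p = 8.8e-22). CCNB1 stood at 261 ± 4.43 and 264 ± 1.42 CPM in NR cells (interaction 0.91, edgeR adjusted p = 0.0043). Sterol genes were above 0 in 16 and below in 0 of 23 cases (median 0.75, camera adjusted p = 6.4e-13), with ACAT2, which starts the pathway, at 1.5. ERK output genes were above 0 in 6 and below in 0 of 24 (median 0.18, camera adjusted p = 0.036, but adjusted p = 0.39 with an estimated correlation), ETV4 at 1.09, a call lost without parental control replicates 1 or 3 (0.11 and 0.084), without parental neratinib replicate 3 (0.056) and with library size scaling (0.068). Within each list alone, counts above and below 0 were 27 and 0, 31 and 0, 17 and 0, and 6 and 1. They were 30 and 0, 34 and 1, 17 and 1, and 12 and 4 without parental control replicate 2.

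ATF4 targets were below 0 in 26 of 37 cases and above in 0 (median -0.85, camera adjusted p = 5.1e-28). INHBE rose from 1.40 ± 0.277 to 35.9 ± 1.55 CPM in parental cells and stood at 1.04 ± 0.219 and 2.06 ± 0.225 CPM in NR cells (interaction -3.59, edgeR adjusted p = 5.7e-05). DDIT4 had -3.10 and ASS1, which makes the precursor of arginine, -2.41. NF-kB genes were below 0 in 13 of 24 and above in 0 (median -0.80, camera adjusted p = 2.7e-10), the chemokine gene CXCL2 at -1.49, and FOXO targets in 10 of 23 and above in 0 (median -0.41, camera adjusted p = 4.4e-06), IRS2 at -1. Genes of glycolysis and HIF gave no call (3 above and 3 below of 24, median 0.02, mean -0.05, camera adjusted p = 0.86), nor did fatty acid genes (3 and 0 of 14, 0.38), lysosome genes (0 and 3 of 29, 0.19), receptor tyrosine kinases (0 and 4 of 21, 0.11) or mTORC1 machinery (1 and 1 of 32, 0.99). Translation gave no call (0 and 2 of 24, camera adjusted p = 0.35), but 18 of its genes were below 0 without parental control replicate 2 (camera adjusted p = 9e-12). With list-wise adjustment, ATF4 targets had 33 below, NF-kB genes 17, FOXO targets 11, glycolysis 4 and 6, fatty acid genes 3 and 1, and lysosome genes 1 and 5, the rest being the same. Counts above and below 0 were 0 and 35 for ATF4, 0 and 18 for NF-kB, 1 and 14 for FOXO, 4 and 7 for glycolysis, 7 and 2 for fatty acid, 3 and 9 for lysosome, 3 and 7 for receptor and 4 and 8 for mTORC1 genes without parental control replicate 2. ERBB3, at 142 ± 21.2, 213 ± 3.28, 100 ± 3.97 and 107 ± 5.42 CPM from parental control to NR neratinib, had an interaction of -0.41 (edgeR adjusted p = 0.045, and 0.00045 without parental control replicate 2). That call was lost without NR control replicates 1, 2 or 3 (0.1, 0.12 and 0.068), NR neratinib replicates 1, 2 or 3 (0.12, 0.068 and 0.1), parental control replicate 1 (0.063) or parental neratinib replicates 1, 2 or 3 (0.11, 0.097 and 0.095), and with the replicate block (0.083). EGFR (0.7) and ERBB2 (0.99) gave no call.

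**Figure D5:**
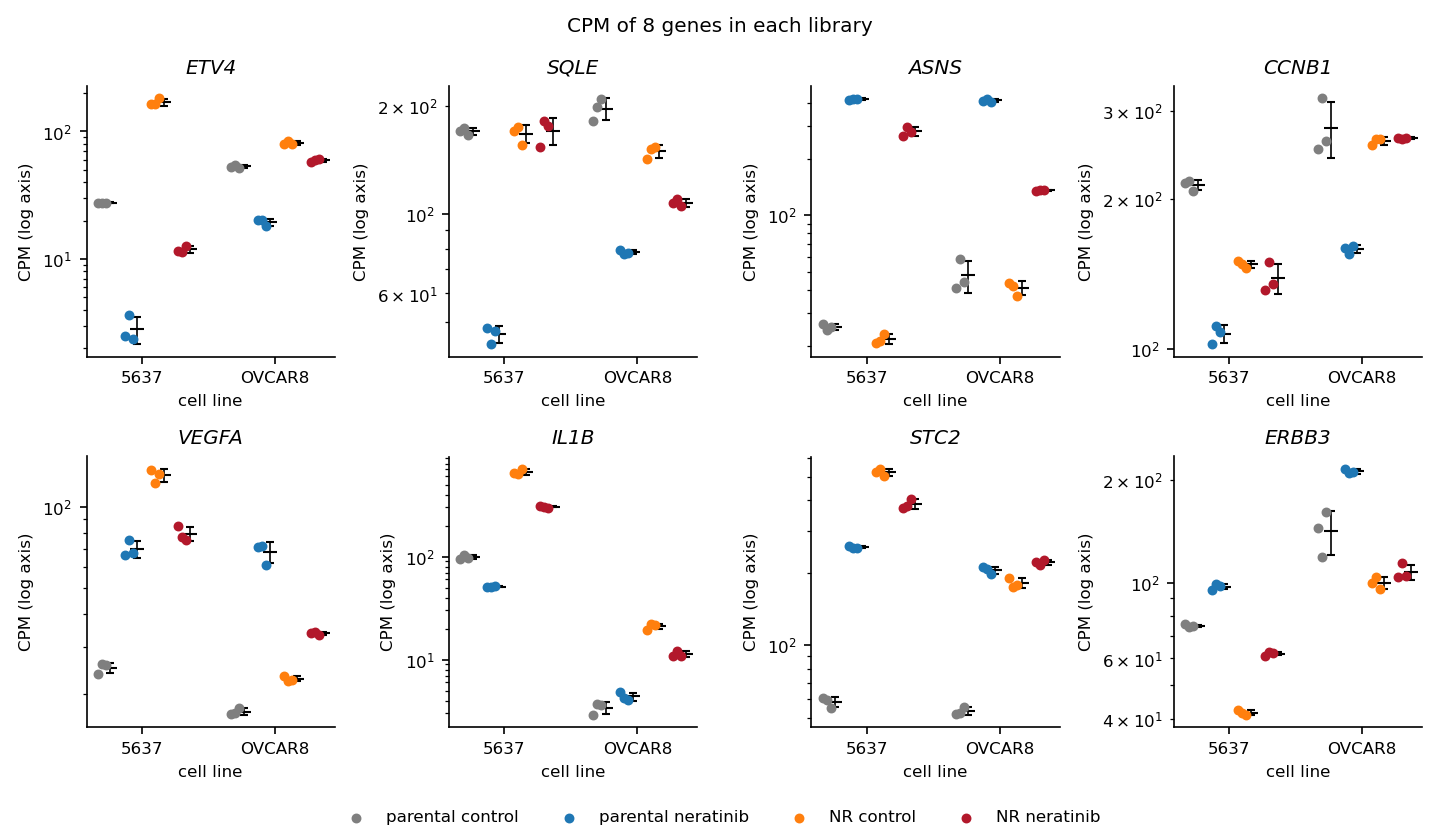
CPM on a log axis for ETV4, SQLE, ASNS, CCNB1, VEGFA, IL1B, STC2 and ERBB3 in the 8 groups, with 1 point per library, a dash for the mean and an error bar for the SD of 3 libraries. SQLE falls from 170 to 46.2 CPM in parental 5637 cells under neratinib and stands at 167 and 171 CPM without and with it in NR 5637 cells.

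NR and parental cells under the drug were compared as a secondary question, to ask how resistant cells differ while exposed. In 5637, 5269 genes rose and 5344 fell by edgeR, with 3165 at least 2-fold. Sterol genes stood higher in NR cells in 22 of 23 cases and lower in 0 (median 1.62, camera adjusted p = 4.2e-11), and mitosis genes in 25 and 0 of 30 (median 0.58, camera adjusted p = 9.6e-09, but adjusted p = 0.072 with an estimated correlation). ERK output genes stood higher in 13 and lower in 4 of 24 (median 0.78, camera adjusted p = 0.016, but adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone these counts were 22 with 1, 26 with 0 and 13 with 5. In OVCAR8, 2638 rose and 2958 fell, with 1237 at least 2-fold, against 4959, 5327 and 1492 without parental control replicate 2, which lies outside this comparison. Mitosis genes stood higher in 28 and lower in 0 of 30 cases (median 0.68, camera adjusted p = 3.1e-17), and ATF4 targets higher in 1 and lower in 33 of 37 (median -0.97, camera adjusted p = 2.7e-20). Adjusted over the list alone these counts were 30 with 0 and 1 with 34.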

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

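Of the tests in this part, the length trend in the deviating library, its effect and that of depth on the OVCAR8 response, list tests without single libraries and the 3 tests on 5637 NR cells were chosen after the result was seen, and the others before.

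The deviating OVCAR8 library, parental control replicate 2, held fewer counts in long genes. With a smooth trend on gene length removed, its spread from its replicates (SD 0.473, or 0.605 before) was still 3.96 times the highest of the 9 OVCAR8 libraries of other groups (0.119), above the bound of 1.5 for length bias as the whole cause. RNA from 5637 cells was argued against by a median level of 0% of the 5637 level over 39 genes high in 5637 and nearly absent from OVCAR8. A wrong label was argued against by a position of 0.0831 toward the nearest other OVCAR8 group, where 1 is that group. What set the library apart stays open, length bias as part of it (38.7% of the variance of its deviation lay on the trend), and no biological explanation was tested.

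OVCAR8 NR cells responded less to neratinib than parental cells, a difference between states found by the interaction. Spread from the deviating library was argued against by a slope of 0.236 without it. The slope over 118 genes with at least 500 counts in every library was 0.311 (0.343 without that library). Neither it nor thinning to equal depth, planned first, decided on lower depth, since folds are scaled to depth and calls follow the shared spread. Choice of genes on the parental response was argued against by 1309 genes chosen in 5637, over which the NR response was 0.268 of the parental one. A changed drug response of NR cells remains as a hypothesis, found and tested on the same data.

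In 5637 NR cells, mitosis, DNA replication and sterol genes responded less while ERK output genes still fell. With library size only, these lists' members had a median 0.639 above all genes in the interaction (lower quartile 0.413). This cannot test scaling, which the subtraction removes. Mitosis genes were little lower in untreated NR cells (median -0.0602, called by fry). Below 0 in lists that fell, interaction medians of glycolysis (-0.267, call lost) and ERK output (-0.389, no call) argue against a uniformly weaker effect there. Under the drug ERK output stood higher in NR than in parental cells (median 0.78, camera adjusted p = 0.016, but 0.28 with an estimated correlation). Remaining ERK output could sustain division and sterol genes, or these may have become less dependent on it, and no value here separates the readings, as ERK activity was not measured.

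These results differed between states or lines by the test of the difference. The 5637 interaction was called in 1352 and 1187 genes and the OVCAR8 interaction in 835 and 760. The lines differed in 1105 and 978 genes for the parental drug effect and in 3003 and 3660 for NR against parental cells. In 5637 the lists (camera adjusted p) were ATF4 1.6e-11, sterol 2.2e-29, fatty acid 4.7e-06, glycolysis 1.3e-05, nucleotide synthesis 1.4e-05, ribosome biogenesis 7e-04, translation 9.1e-07, DNA replication 3.4e-16, mitosis 2.9e-30, urothelial 0.0043, interferon 0.0058, apoptosis 0.026 and oxidative phosphorylation 5.8e-05. Lost there were glycolysis, ribosome biogenesis, translation, urothelial, apoptosis and oxidative phosphorylation (adjusted p = 0.05, 0.26, 0.06, 0.13, 0.2 and 0.13 with an estimated correlation). In OVCAR8 they were ERK output 0.036, FOXO 4.4e-06, ATF4 5.1e-28, sterol 6.4e-13, nucleotide synthesis 0.00013, ribosome biogenesis 8.2e-07, DNA replication 8.8e-22, mitosis 3.6e-22, NF-kB 2.7e-10, mitochondrial mRNAs 0.0029 and oxidative phosphorylation 6.4e-06. Lost there were ERK output, nucleotide synthesis, ribosome biogenesis, mitochondrial mRNAs and oxidative phosphorylation (adjusted p = 0.39, 0.063, 0.063, 0.38 and 0.5 with an estimated correlation). Between lines under the drug they were ERK output 2.8e-30, ATF4 0.0045, sterol 5.2e-06, nucleotide synthesis 0.0055, ribosome biogenesis 2.8e-06, mitosis 8e-05, receptors 0.0046, NF-kB 4e-11, YAP 0.0093, NRF2 6.4e-06 and xenobiotic metabolism 0.00012. Lost were ATF4, nucleotide synthesis, ribosome biogenesis, mitosis, receptors and YAP (adjusted p = 0.24, 0.16, 0.05, 0.083, 0.33 and 0.44 with an estimated correlation). For NR against parental cells they were ERK output 0.0093, FOXO 0.0014, glycolysis 6.4e-06, lysosome 0.014, DNA replication 0.047, growth factors 0.026, basal 0.026, antigen presentation 0.0053, NF-kB 7.3e-05 and unfolded protein response 3.7e-07. All but glycolysis and the last were lost (adjusted p = 0.36, 0.064, 0.15, 0.4, 0.064, 0.36, 0.11 and 0.055 with an estimated correlation). Without the deviating library the calls for receptors (0.12), YAP (0.47), growth factors (0.053) and basal genes (0.12) were lost. Calls were gained for translation (0.00063), unfolded protein response (0.0031) and oxidative phosphorylation (0.036) under the drug and for translation (1.9e-08) and YAP (0.00018) for NR against parental cells.

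Single genes in the 5637 interaction (log2) were MPPED2 3.59, FGFBP1 2.5, WNT10A 2.43, DIO2 2.42, PELI2 -2.98, STC2 -2.60, CHAC1 -2.45, PTGS2 -2.29 and TMEM200A -2.21. PELI2 was lost without any of 9 libraries. In OVCAR8 they were ACAT2 1.5, MT-TL2 1.44, TFRC 1.42, ADM 1.34, INHBE -3.59, DDIT4 -3.10, ASS1 -2.41, EPAS1 -1.98, TRIB3 -1.92 and ERBB3 -0.41.

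Among splits of the libraries into groups of the same sizes, the real one included, few called as many genes as the real split. These were 4 of 100 for the interactions in 5637 (2539 genes, highest other 3944) and OVCAR8 (1595, 2628). Between lines they were 1 of 40 for NR against parental cells (6663, 5873) and 2 of 40 for the drug effect (2083, 3403). Redrawing the labels also broke up the effects within each state or line. A low share could follow from those effects alone, so chance is not excluded for these differences. Splits with more genes left 1 pair of groups whole and mostly swapped the other, so they carried the drug effect itself. For each comparison of 3 against 3 the 10 splits are too few for a share under 0.05, and 1 split, the real one, was as large, with 0 genes as the highest other. The real counts were 8665, 10339, 7230 and 10613 in 5637 and 5868, 1779, 251 and 5596 in OVCAR8.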

How the results depend on the processing

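The fits without OVCAR8 parental control replicate 2 for overlaps, lists and the drug effect in OVCAR8 NR cells, and those leaving out libraries for lists and for differences between lines, were chosen after seeing the data. Where the text gives no cause, the cause was not tested. No called gene was reversed. EGFR, near 0 and not called, changed sign in 4 fits of the drug effect in NR 5637 cells and in 1 of the OVCAR8 interaction. Counts outside those listed stayed within 1.5 times the main count. Of 576 named results, weaker ones numbered 42 with the 6 libraries compared alone, 34 with all 24 libraries, 21 with library size only, 16 with the replicate block, 15 with no filter, 6 with voom, 3 with size factors, 3 with robust dispersion and 299 over libraries left out. Of 135 called or described lists 60 were weaker with an estimated correlation and 75 were not. With fry 10 were stronger and 5 weaker, with library size only 1 and 6, and over libraries left out 6 and 22. Fry called ATF4, ribosome biogenesis, DNA replication, mitosis and receptor genes in 5637 NR against parental cells (0.00016, 0.0065, 1e-04, 0.0027 and 0.0076), where camera did not and members went both ways. It also called receptors in parental 5637 cells (0.011), ERK output, FOXO and lysosome genes in the 5637 interaction (0.0094, 0.023 and 0.0043) and lysosome genes in the OVCAR8 interaction (0.021). It lost mitochondrial mRNAs in parental 5637 cells (0.12) and oxidative phosphorylation in OVCAR8 NR against parental cells (0.33) and the OVCAR8 interaction (0.14).

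A 1 CPM filter tests fewer genes, and gave 1129 genes at least 2-fold in parental 5637 cells under the drug, 722 in parental OVCAR8 cells and 822 in OVCAR8 NR against parental cells with drug. With the 6 libraries compared alone, OVCAR8 gave 1560 rising and 1305 falling for the parental drug effect, 236, 254 and 291 (at least 2-fold) for NR against parental, 1633, 2008 and 107 for the NR drug effect, and 5222 and 5179 with drug. These fits of the NR drug effect and with drug leave out parental control replicate 2, whose removal alone gave 1740 and 2210, and 4959 and 5327. With all 24 libraries, OVCAR8 gave 1409 and 1475 for NR against parental, 260, 228 and 65 for the NR drug effect and 1289 and 1147 for the interaction, and the 5637 interaction gave 712 and 747. DESeq2 gave 377, 423 and 64 for the OVCAR8 NR drug effect, 1406 rising in the OVCAR8 interaction, and 310 and 277 genes shared by the drug effects in OVCAR8. Library size only gave 2428 falling in 5637 NR cells under the drug. Counting genes of at least 2-fold only, overlaps were 62 and 40 for NR against parental cells between lines, 276 and 91 for the parental drug effect between lines, 394 and 219 for parental and NR drug effects in 5637 and 18 and 5 in OVCAR8.

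Replicate numbers did not pair samples. Deviations of libraries with the same number had r from -0.16 to 0.13 in 5637, with 3 of 12 libraries closest to their own number, and -0.12 to 0.11 in OVCAR8, with 5 of 12. Used as a block, they gave 46, 52 and 19 genes for the OVCAR8 NR drug effect.

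Leaving out 1 library at a time, where an arm of 2 shares the pooled spread, OVCAR8 counts ran from 2169 to 4506 rising and 2038 to 4611 falling for the parental drug effect, 503 to 2118 and 490 to 2107 for NR against parental, 21 to 1740 and 22 to 2210 (14 to 139 at least 2-fold) for the NR drug effect, 409 to 3157 and 375 to 2919 (221 to 607) for the interaction, and 1827 to 4959 and 2063 to 5327 with drug. The drug effect between lines ran from 798 to 2017 and 602 to 1852. Overlaps without parental control replicate 2 were 844 and 743 for NR against parental between lines and 1131 and 1241 for the drug effects in OVCAR8. Each highest value is the one without that library, where the biological coefficient of variation in OVCAR8 was 4.37% against 13% with it. The reversed list was oxidative phosphorylation in OVCAR8 NR against parental cells (camera adjusted p = 0.84 without it, and 0.00014 at the lowest without another). Depth limits genes of few counts, such as MPPED2 and PELI2 in 5637 NR cells.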

Other observations

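No hypothesis was tested in this part, and of its tests the list tests without single libraries, the deviating one among them, were chosen after the result was seen. In 5637 cells genes of detoxification moved with the drug. In parental 5637 cells NRF2 targets, genes of the antioxidant response, rose in 15 and fell in 6 of 25 cases (median 0.93, camera adjusted p = 0.00025), among them the cystine transporter SLC7A11 and the exporter ABCC3 (log2 2.25). Xenobiotic metabolism genes rose in 12 and fell in 4 of 23 (median 0.34, camera adjusted p = 0.0033), CYP4F3 by 2.16 and CYP1A1 by 1.91. In NR 5637 cells these lists rose in 18 with 3 falling (camera adjusted p = 2.2e-09) and in 11 with 1 falling (1e-04), and AKR1C1, which shares reads with near-identical copies, went from 5.61 ± 0.238 to 39.6 ± 3.18 CPM. ABC transporters rose in 8 and fell in 2 of 15 in parental cells (camera adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation). In parental OVCAR8 cells NRF2 targets gave no call (camera adjusted p = 0.075, and 0.025 without parental control replicate 2).

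Interferon genes rose under the drug in NR 5637 cells, in 19 with 2 falling of 36 (median 0.40, camera adjusted p = 3.2e-05). The OVCAR8 NR call was lost with an estimated correlation (0.13). Untreated NR 5637 cells had more unfolded protein response mRNA, 18 of 21 genes rising and 0 falling (median 0.57, camera adjusted p = 1.4e-07). Of 16 antigen presentation genes 8 rose and 1 fell (camera adjusted p = 0.021, adjusted p = 0.25 with an estimated correlation), CD74 from 29.4 ± 2.38 to 316 ± 29.5 CPM and its regulator CIITA by 3.11. YAP targets rose in 15 and fell in 5 of 23 (camera adjusted p = 0.012, adjusted p = 0.28 with an estimated correlation). In OVCAR8 NR cells under the drug the YAP call (0.045, adjusted p = 0.58 with an estimated correlation) was also lost with fry (0.27), library size scaling (0.052) and the replicate block (0.066), and without NR control replicates 1 or 2 (0.12 and 0.051) or NR neratinib replicate 2 (0.068).

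With adjustment over the list alone, NRF2 targets in NR 5637 cells had 4 falling, interferon genes 20 rising and ABC transporters in parental cells 3 falling, and the other counts printed here were the same. Marker lists of other cell types were read per library. The mean log2(CPM+1) of blood and immune markers was 0.125 to 0.215 in 5637 and 0.252 to 0.364 in OVCAR8, and that of fibroblast markers 2.06 to 2.7 and 1.48 to 1.72.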
